A study of Mus musculus with 8 samples.

How the data were processed

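The series profiled bone marrow cells of mice by droplet single-cell RNA sequencing (10x Genomics Single Cell 3' v3.1). Per the labels' protocols, marrow from 3 mice per condition was tagged with hashing antibodies, depleted magnetically of cells bearing CD11b, GR1, TER119, B220 or CD3, pooled by condition and sorted into viable, lineage-negative GFP-positive and GFP-negative populations. The proportion in which the sorted populations were loaded is not stated. Per the submitters' processing notes, reads were processed with Cell Ranger 4.0.0 on mm10, and Seurat 4.0.4 is named without a role. The deposited values are counts: raw UMI counts per gene and cell barcode, with no normalisation, and cell barcodes had already been called. The 4 libraries of hashing tags were not among the data analysed here, so cells could not be traced to single mice. A library is therefore 1 sample, and the groups were taken from the sample titles.

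Each matrix held 31054 features including GFP, and 31011 gene identifiers matched GENCODE M21 (GRCm38, the same assembly as mm10), which gave the coordinates. Cells were kept with at least 500 genes, at least 1000 UMIs and under 10% mitochondrial UMIs. The barcodes at or above 10% mitochondrial UMIs made up 30.5%, 31.7%, 25.1% and 22.0% of the libraries. Doublets were scored with Scrublet in scanpy, and the highest-scoring 0.8% per 1000 barcodes were removed, which took 761, 165, 200 and 501 cells. The 4 libraries were clustered together with scanpy 1.11.5 (anndata 0.12.19, igraph 0.11.9, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, Python 3.11.15; figures with matplotlib 3.10.9): counts scaled to 10000 per cell and log-transformed, 2000 variable genes without sex-linked marker genes and GFP, 30 principal components, 15 neighbours and Leiden clustering at resolution 1.0, with no batch correction. This gave 31 clusters.

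Clusters were named from 18 sets of markers fixed before the data were examined, and a name means that a cluster resembles the type by those markers. A named cluster needed a mean marker score of at least 0.5, at least 3 markers detected at 50 CPM, a margin of 0.2 to the next class and at least 2 markers among its 10 leading genes. The last 2 limits were set after the clusters had been seen. Clusters 2, 4, 5, 9, 10, 13, 14 and 18 stayed unnamed. In the order wild type with JAK2WT, wild type with JAK2V617F, Gli1 knockout with JAK2WT and Gli1 knockout with JAK2V617F, cluster 2, led by histone and cell cycle genes, took 1.30%, 7.19%, 7.98% and 10.7% of kept cells. Cluster 4 took 3.35%, 0.553%, 6.08% and 1.12%. Cluster 5, of low UMI counts, took 0.996%, 0.931%, 18.5% and 2.64%, and cluster 13, also of low UMI counts, 22.6%, 0.116%, 0.605% and 0.718%. Cluster 9 took 0.484%, 1.19%, 1.13% and 1.94%, and cluster 10 took 4.17%, 0.466%, 3.95% and 0.601%. Cluster 14 took 9.56%, 0.815%, 4.92% and 2.19%, and cluster 18 took 2.52%, 0.436%, 0.579% and 0.117%. Pf4, a platelet gene, led HSC/MPP cluster 6, and Ccl5 and Gzma led T cell cluster 12.

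Shares are percentages of all kept cells with exact Clopper-Pearson 95% intervals, and ratios of shares carry log-normal intervals for the ratio of binomial shares. Expression was compared within classes that had at least 100 kept cells in each of the 4 libraries: HSC/MPP, NK and innate lymphoid, granulocyte-monocyte progenitor and promyelocyte, and monocyte. Raw counts were summed per library and class and given as CPM with exact Poisson intervals. Composition-standardised CPM is the mean of the class CPM with the same weights in every library (35.1%, 13.9%, 34.0% and 17.0%, the mean class shares), with the gamma interval of Fay and Feuer. Log2 ratios had 10 CPM added to both values. The median log2 ratio of all measured genes was 0.05, -0.01, 0.04 and 0.00 in the comparisons JAK2V617F over JAK2WT in wild type, Gli1 knockout over wild type with JAK2V617F, Gli1 knockout over wild type with JAK2WT, and JAK2V617F over JAK2WT in Gli1 knockout. Cells are not replicates, so no p-value was computed.

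There were 25 gene lists fixed before the data were examined. A list's value is the median log2 ratio over members with at least 10 CPM in either library, with an interval from 200 Poisson redraws of the counts and a percentile among 10000 random lists of the same size matched on mean expression. Named genes followed a rule fixed at the same time. For each comparison it takes the 6 highest and 6 lowest standardised log2 ratios among genes with at least 50 CPM in either library whose class ratios share that sign in at least 0.75 of the classes. In each class it adds the 2 highest and 2 lowest ratios among genes with at least 100 CPM and 30 counts in the higher library. It adds Gli1, Jak2, Mif, Cd74 and the 2 highest and 2 lowest abundant members of each list quoted. Mitochondrial, ribosomal protein, predicted, haemoglobin, immunoglobulin and T cell receptor segment genes, Xist, Tsix and Y-linked genes were not eligible. The rule sets which genes may be named, and many of the genes it takes, most of them list members, are not reported here. Xist, Y-linked and immunoglobulin counts, Hbb-bs and the Lcn2 value in Gli1 knockout were added to the text after their values were seen. A test of free erythroid RNA on the JAK-STAT members lower in erythroid cells, laid down beforehand, was replaced by one on all measured members, because the library that set the split also enters the ratio.

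The procedure was tested on simulated data with 200 genes altered by a known amount. It put all of them in the right direction, and none of 2778 unaltered genes reached 1.5-fold in any comparison. The intervals covered the true value for 95.5% to 96.2% of 2978 genes. The simulated counts of both libraries were Poisson draws from the same class profiles, without variation between mice, pools or cell class calls. These results therefore bear on counting error only, not on differences between unreplicated libraries. Alternatives changed the cell filter, the doublet share, the clustering, the scaling, the pseudocount, the list filter, the class weights, the classes used and the depth per cell (thinned to 1000 UMIs). Another 6 were added after the data had been seen: clusters as strata, 2 other denominators of the shares, cluster 2 counted with HSC/MPP, a wider naming of clusters, and scaling without immunoglobulin, haemoglobin, S100a8 and S100a9.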

Results

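Bone marrow was profiled cell by cell in a mouse model of myeloproliferative neoplasm, a blood cancer in which marrow scarring can follow. Irradiated female recipients had received marrow from wild type donors or from donors lacking Gli1, a transcription factor of the hedgehog pathway. The donor cells had been transduced with a retrovirus carrying JAK2V617F, the constitutively active kinase common in these neoplasms, or unmutated JAK2 (JAK2WT). The series asks what Gli1 in blood-forming cells does in JAK2V617F-driven myelofibrosis. Each of the 4 combinations of genotype and transduction was 1 library made from the pooled marrow of 3 mice taken 112 days after transplantation, so n = 1 per group and no difference below has a replicate check or a test. Throughout, the groups are given in the order wild type with JAK2WT, wild type with JAK2V617F, Gli1 knockout with JAK2WT and Gli1 knockout with JAK2V617F. The libraries held 12376, 5907, 7155 and 8762 barcodes with 72458173, 59165347, 84063880 and 114847114 UMIs. After filtering, 7226, 3437, 3799 and 5989 cells were kept, with medians of 4410, 13101, 17266 and 13841 UMIs per cell. Ranges in parentheses are 95% intervals that cover counting error only.

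Gli1 itself (chromosome 10, 127329882 to 127341974, minus strand, mm10) was close to undetected in every library, so the knockout could not be checked on its own transcript. Kept cells held 0, 2, 4 and 5 Gli1 UMIs. In the Gli1 knockout libraries all 4 and all 5 of these UMIs lay in mesenchymal stromal cells, which numbered 59 and 48. The remaining 3740 and 5941 cells held 0. Many of these stromal cells may stem from the female recipients (see Other observations), so the UMIs need not come from donor cells. Jak2, the gene named by the transduction (chromosome 19, 29251828 to 29313080), measured 39.8 (34.8 to 45.4), 37.6 (32.6 to 43.4), 33.9 (30.04 to 38.1) and 28.6 (26.9 to 30.5) CPM (UMI counts scaled to a common total per library) after standardisation for cell class. A 3' library does not separate the mutant from the normal transcript. Xist, transcribed from the inactive X chromosome, had 78124, 36608, 1023 and 335 UMIs in kept cells, and Y-linked genes had 1, 0, 9089 and 11925. The genotypes therefore differed in the sex of the donor cells as well as in Gli1, and this holds for every genotype comparison below.

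Erythroid-like cells, which carry haemoglobin and red cell membrane genes, set wild type marrow with JAK2V617F apart from the other libraries. They made up 1.08% (0.854 to 1.35) of kept cells in wild type marrow with JAK2WT, 35.5% (33.9 to 37.2) with JAK2V617F, 1.32% (0.978 to 1.73) in Gli1 knockout marrow with JAK2WT and 1.02% (0.780 to 1.31) with JAK2V617F. The share was 32.9-fold higher (26.3 to 41.2) with JAK2V617F in wild type marrow. In Gli1 knockout marrow the ratio was 0.774 (0.534 to 1.12). HSC/MPP-like cells, the stem and multipotent progenitors, took 3.60%, 12.2%, 11.8% and 34.4% of the kept cells. Their share was 3.39-fold higher with JAK2V617F in wild type and 2.92-fold higher in Gli1 knockout marrow. Granulocyte-monocyte progenitors and promyelocytes took 4.73%, 16.9%, 15.1% and 13.3%, which is 3.57-fold higher with JAK2V617F in wild type and 0.879-fold in Gli1 knockout marrow. Neutrophil-like cells took 1.76%, 5.67%, 0.632% and 4.39%, and mast cell and basophil-like cells 1.38%, 5.73%, 2.05% and 6.26%. Monocyte-like cells took 4.98%, 3.61%, 6.53% and 5.81%, and natural killer (NK) and innate lymphoid-like cells 2.34%, 4.92%, 4.42% and 10.2%.

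Lymphoid cells stood apart in wild type marrow with JAK2WT. T cell-like cells made up 16.5% of it and 0.727%, 1.45% and 1.29% of the other libraries. B lineage-like cells made up 9.67%, 0.204%, 0.158% and 0.818%. Plasma cell-like cells took 4.14%, 0.960%, 9.71% and 1.00%, and plasmacytoid dendritic-like cells 2.73%, 0 of 3437 cells (which allows up to 0.107%, the upper bound of the exact interval), 0.421% and 0.134%. Under the wider naming of clusters, the plasmacytoid ratio of Gli1 knockout to wild type with JAK2WT went from 0.154 to 1.02. Mesenchymal stromal-like cells took 0.609%, 1.57%, 1.55% and 0.802%. Macrophage-like cells took 0.900%, 0.0873%, 0.447% and 0.117%, and conventional dendritic-like cells 0.567%, 0.204%, 0.684% and 0.451%. The depletion of CD11b, GR1, TER119, B220 and CD3 and the sorting by GFP set these shares in part, and the first library was the shallowest per cell. Counted without lymphoid, plasma cell, plasmacytoid and low-UMI clusters, the ratios with JAK2V617F in wild type were 14.7 for erythroid cells, 1.51 for HSC/MPP and 1.59 for granulocyte-monocyte progenitors. Under other cell filters, doublet shares or clustering the monocyte ratio with JAK2V617F in wild type ranged down to 0.115, and that of granulocyte-monocyte progenitors in Gli1 knockout to 0.569.

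**Figure D1:**
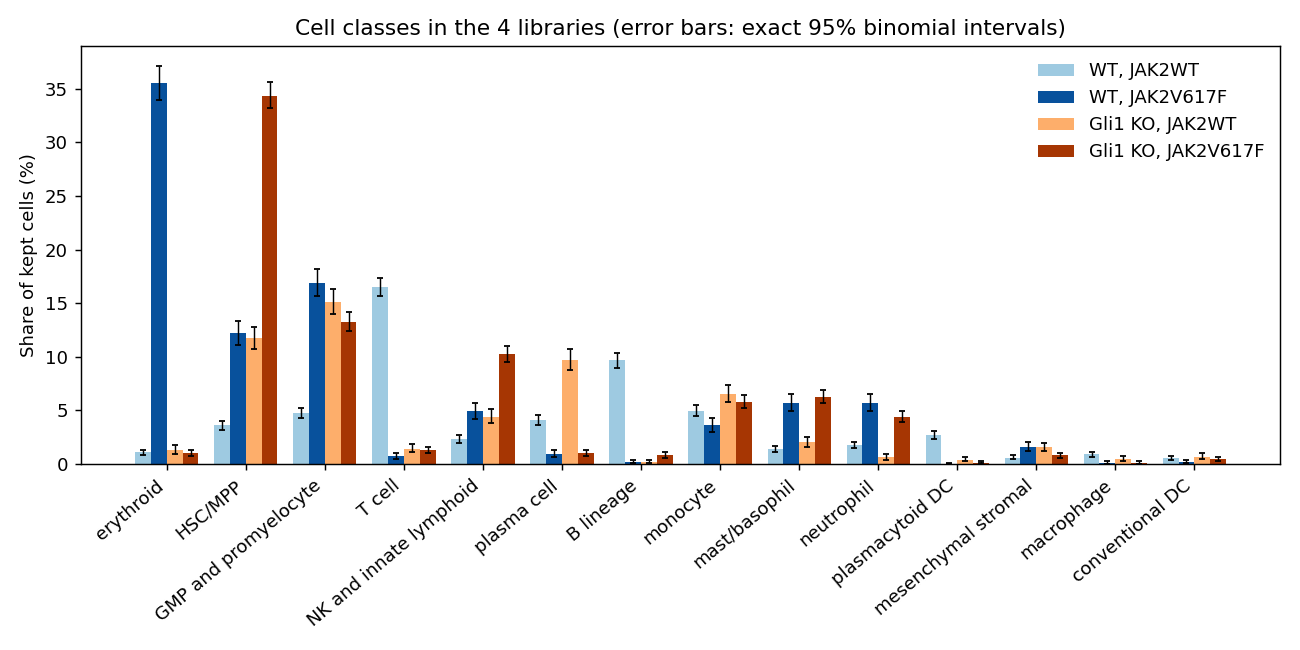
Share of kept cells in percent, as bars, for each named cell class in the 4 libraries, with exact 95% binomial error bars for counting error. Erythroid-like cells stand at 35.5% in wild type marrow with JAK2V617F and near 1% in the other libraries.

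The first comparison set JAK2V617F against JAK2WT in wild type marrow and asks what the mutant kinase does to blood-forming cells with Gli1 intact. Its JAK2WT library is also the wild type side of the fourth comparison, so a departure of that library would enter both. In all 4 matched cell classes the medians of JAK-STAT target, glycolysis and MYC-related genes were higher with JAK2V617F. Those of cholesterol synthesis genes were higher in 3 of the 4 classes, and those of alarmin and profibrotic ligand genes were lower in 3 of the 4. The highest ratios were those of Lcn2, which codes for the iron-scavenging protein lipocalin 2, and Ifitm1, an interferon-inducible membrane protein. Lcn2 (chromosome 2, 32384633 to 32388252) was 16.1 CPM with JAK2WT and 123.5 CPM with JAK2V617F (log2 ratio 2.35), and Ifitm1 (chromosome 7, 140967221 to 140969825) was 198.9 and 1003 CPM (2.28). Lcn2 was among the fixed neutrophil markers and Ifitm1 among the fixed HSC/MPP markers, and both were compared here within cell classes. Junb, an AP-1 subunit and JAK-STAT target, stood at 1.22, Ldha, which makes lactate from pyruvate, at 1.17, Emilin2 at 1.13 and Tespa1 at 1.06.

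Of 24 JAK-STAT target genes, 22 were measured in this pair. Their median log2 ratio was 0.29 (0.23 to 0.44), at percentile 99.96 of random lists matched on size and expression, a percentile that describes these 2 libraries and not a population of mice. Of the 22, 8 were at least 1.5-fold higher and 1 at least 1.5-fold lower. The median was 0.58 in granulocyte-monocyte progenitors, 0.36 in monocytes, 0.19 in HSC/MPP and 0.19 in NK and innate lymphoid cells. Pim1, a survival kinase induced by STAT5, went from 43.6 to 188.3 CPM in granulocyte-monocyte progenitors (log2 1.89) and from 63.3 to 229.5 CPM in monocytes (1.71). Among members with at least 50 CPM, the lowest were the cyclin Ccnd2 (log2 -0.37) and Cdc25a (-0.11). Without standardisation, in sums over all kept cells, the list's median was -0.04. It was 0.12 with 50 CPM added to both values and 0.61 over members with at least 50 CPM.

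Glycolysis and hypoxia genes had a median of 0.57 (0.43 to 0.63), with 9 of 19 at least 1.5-fold higher, led by Ldha and Pkm (0.86). Cholesterol synthesis stood at 0.40, with Idi1 at 0.75 and Fdps at 0.70, but at -0.26 in NK and innate lymphoid cells. MYC and ribosome biogenesis genes stood at 0.34, with Myc at 0.67 and Nolc1 at 0.64. Heme synthesis and globin genes stood at 0.39, and erythroid progenitor genes at 0.32, with the transferrin receptor Tfrc at 0.83. Haemoglobin RNA outside the erythroid class, which may be free RNA, moved with these lists. Hbb-bs was 1.76 CPM with JAK2WT and 36.2 CPM with JAK2V617F in granulocyte-monocyte progenitors, and 9528 CPM in the erythroid-like cells of the latter library. Unfolded protein response genes stood at 0.24 with Sdf2l1 at 0.66, p53 targets at 0.20 with Bax at 0.45, and S phase genes at 0.15 with Rrm2 at 0.88, but at -0.74 in NK and innate lymphoid cells. The list of immediate early and dissociation stress genes stood at 0.32 with Hspa8 at 0.94, but at -0.28 in sums over all kept cells.

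Alarmin and neutrophil inflammation genes had a median of -0.43 (-0.52 to -0.32), but of 0.18 in HSC/MPP. S100a8 and S100a9, the calprotectin subunits and fixed neutrophil markers, stood at -1.97 and -1.53, and Slpi, an elastase inhibitor, at -1.30. In sums over all kept cells, of which neutrophils were a 3.23-fold larger share with JAK2V617F, this list stood at 1.19, with S100a8 at 0.97 and S100a9 at 1.253. Profibrotic ligands had a median of -0.43 (-0.51 to -0.32) over 10 of 28 members measured, 0.15 in monocytes, and 0.02 in the sums over all cells. Among them, Pf4, the platelet chemokine CXCL4, stood at -2.17 and the chemokine Ccl5 at -0.53, while Lcn2 stood at 2.35 and Tgfb1 at 0.44. The Pf4 value came from HSC/MPP cells, where Pf4 leads a cluster and went from 353.4 to 53.8 CPM; without that class it was 0.13. HSC-associated genes stood at -0.27, with the stem cell regulators Hlf at -0.98 and Meis1 at -0.38, and at 0.30 in the sums over all cells. They were lower in HSC/MPP only (-0.49), against 0.26 in NK and innate lymphoid cells, 0.15 in granulocyte-monocyte progenitors and 0.77 in monocytes. Oxidative phosphorylation stood at -0.14, and genes of the G2 and M phases at -0.18, with Nusap1 at -1.05. In NK and innate lymphoid cells the G2 and M list stood at -2.04, with 30 of 30 genes at least 1.5-fold lower, and in HSC/MPP at -0.12, granulocyte-monocyte progenitors at 0.01 and monocytes at 0.26. Other lists lay nearer 0: mast cell and basophil 0.12, TGF-beta response 0.11, megakaryocyte and platelet 0.08, MHC class II 0.05, NF-kB 0.05, casein kinase 2 and other reported non-canonical GLI regulators 0.03, interferon response -0.01 and primary granule genes -0.05. Single classes lay further off, with MHC class II at -1.04 in monocytes and primary granule genes at -0.81 in NK and innate lymphoid cells.

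For the hedgehog pathway, 3 of 22 genes reached 10 CPM, with a median of -0.12 (-0.24 to 0.09). The MIF axis stood at 0.03: the cytokine gene Mif (chromosome 10, 75859353 to 75860240) was 855.8 and 916.3 CPM (0.10), its receptor Cd74 130.9 and 155.1 CPM (0.23), and the co-receptors Cd44 and Cxcr4 stood at -0.68 and -0.61. The MIF list was negative without the NK and innate lymphoid class, with the stricter cell filter and in sums over all kept cells. Without HSC/MPP it was higher (values in the section on processing). Ly6c2, a marker of inflammatory monocytes, was lower at -1.56, as were Lars2 (-1.29) and Jchain (-2.79), a plasma cell transcript. In single classes, Cd74 stood at -1.41, Ssbp4 at 1.03 and Ms4a3 at 1.03 in HSC/MPP; Ifitm3 at 1.23, Malat1 at -1.16 and Ankrd28 at -1.08 in granulocyte-monocyte progenitors. In monocytes the metallothionein Mt1 stood at 1.46, the lysozyme gene Lyz2 at -2.15 and Mpeg1 at -1.92, and Lyz2 took the opposite sign under 3 of the alternatives. In NK and innate lymphoid cells, Prnp stood at 3.07, Ddit4 at 2.13, Cenpf at -3.78 and the granzyme gene Gzma at -5.14, beside T cells, whose cluster 12 Gzma leads, at 16.5% and 0.727% of the libraries. This class pools cluster 0, with 116, 123, 88 and 398 cells in the 4 libraries, and cluster 21, with 53, 46, 80 and 215. Clusters 3, 19 and 20 held 111, 153 and 78 cells of the granulocyte-monocyte progenitor class with JAK2WT and 119, 260 and 202 with JAK2V617F.

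The second comparison set the same pair of transductions against each other in Gli1 knockout marrow, to see what JAK2V617F does when blood-forming cells lack Gli1. Ifitm1 was again higher with JAK2V617F, at 294.5 and 774.3 CPM (log2 1.37), and so was Pim1 in granulocyte-monocyte progenitors (67.1 and 153.7 CPM, 1.09) and in monocytes (70.5 and 234.5 CPM, 1.60). Lcn2 was 17.5 and 40.8 CPM (0.89). Jchain was lower at -2.40, Ccl5 at -1.60, Ly6c2 at -0.86, Lars2 at -0.80, the class I gene H2-Q7 at -0.70 and Irf8, a regulator of monocyte and dendritic cell fate, at -0.64. The nucleotide kinase Nme2 stood at 0.98, the protease Ctsc at 0.67, S100a8 at 0.58 and Ifitm3 at 0.54.

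Several lists that stood apart in wild type marrow had standardised medians closer to 0 here. This pair does not hold the wild type library with JAK2WT, which enters the first comparison. JAK-STAT targets had a median of 0.05 (-0.003 to 0.10), with none of 21 measured members 1.5-fold apart in either direction; the class medians were 0.29 in granulocyte-monocyte progenitors, 0.14 in HSC/MPP, 0.08 in monocytes and -0.25 in NK and innate lymphoid cells. Without the NK and innate lymphoid class the median was 0.18, and in sums over all kept cells it was 0.30. Glycolysis stood at 0.11 with Ldha at 0.44, cholesterol synthesis at 0.05, MYC and ribosome biogenesis at 0.10, alarmins at 0.07 and profibrotic ligands at 0.12. In single classes, alarmins stood at 0.67 in HSC/MPP, with 6 of 10 at least 1.5-fold higher, 0.34 in granulocyte-monocyte progenitors, 0.28 in NK and innate lymphoid cells and -0.05 in monocytes, and profibrotic ligands at 0.53 in monocytes. Neutrophils, whose fixed markers include S100a8, S100a9 and Lcn2, were 6.95-fold more frequent with JAK2V617F in this pair. Megakaryocyte and platelet genes stood at 0.21 (0.15 to 0.25), with Cd9 at 0.34 and Nrgn at 0.23, and mast cell and basophil genes at 0.17. MHC class II genes, which present antigen, were lower at -0.41 (-0.43 to -0.27), with H2-Ab1 and H2-DMb1 both at -0.42. In HSC/MPP alone, H2-Aa stood at -1.11 and Cd74 at -1.01. Primary granule genes stood at -0.17, with Ctsg at -0.48 and Mpo at -0.48, and G2 and M phase genes at -0.15, with -0.34 in granulocyte-monocyte progenitors and 0.51 in NK and innate lymphoid cells. The remaining lists lay between -0.04 and 0.10, with immediate early genes at 0.55 in granulocyte-monocyte progenitors; hedgehog genes had 2 members measured (0.00), and the MIF axis stood at -0.04 with Mif at 720.8 and 767.9 CPM.

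Single classes of Gli1 knockout marrow showed further differences with JAK2V617F. HSC/MPP had S100a6 at 1.29 and Ms4a3 at 0.78. Granulocyte-monocyte progenitors had Fos at 1.09, the proliferation marker Mki67 at -0.77 and the linker histone Hist1h1e at -0.76. Monocytes had Dmkn at 1.24, Cd93 at -1.11 and Bcl2 at -0.91, and NK and innate lymphoid cells had Ifitm2 at 1.85, Hist1h1b at 1.39, Arl4d at -1.40 and S100a4 at -1.24. The granulocyte-monocyte progenitor class held 214, 192 and 168 cells of clusters 3, 19 and 20 with JAK2WT and 124, 260 and 411 with JAK2V617F, and Ccl5 rests on the NK and innate lymphoid class: without it the value was 0.33. Set against each other, the JAK2V617F ratio of the knockout minus that of the wild type was -0.25 for JAK-STAT targets, -0.46 for glycolysis, -0.35 for cholesterol synthesis, -0.45 for MHC class II, 0.49 for alarmins and 0.55 for profibrotic ligands (log2 medians). These differences were not tested. The wild type library with JAK2WT is the denominator of the wild type ratios and of the genotype comparison with JAK2WT. In the latter, without the mutant kinase, the same lists stood at 0.11, 0.27, 0.02, 0.32, -0.59 and -0.24. For cholesterol synthesis the JAK2WT libraries lay close together (-0.03 to 0.13), while the JAK2V617F libraries lay apart at -0.30. These values argue against a departure of the wild type library with JAK2WT alone for that list. A departure of the wild type library with JAK2V617F stays open there. For the other lists, a departure of the wild type library with JAK2WT cannot be told apart from a genotype difference in the response to JAK2V617F.

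**Figure D2:**
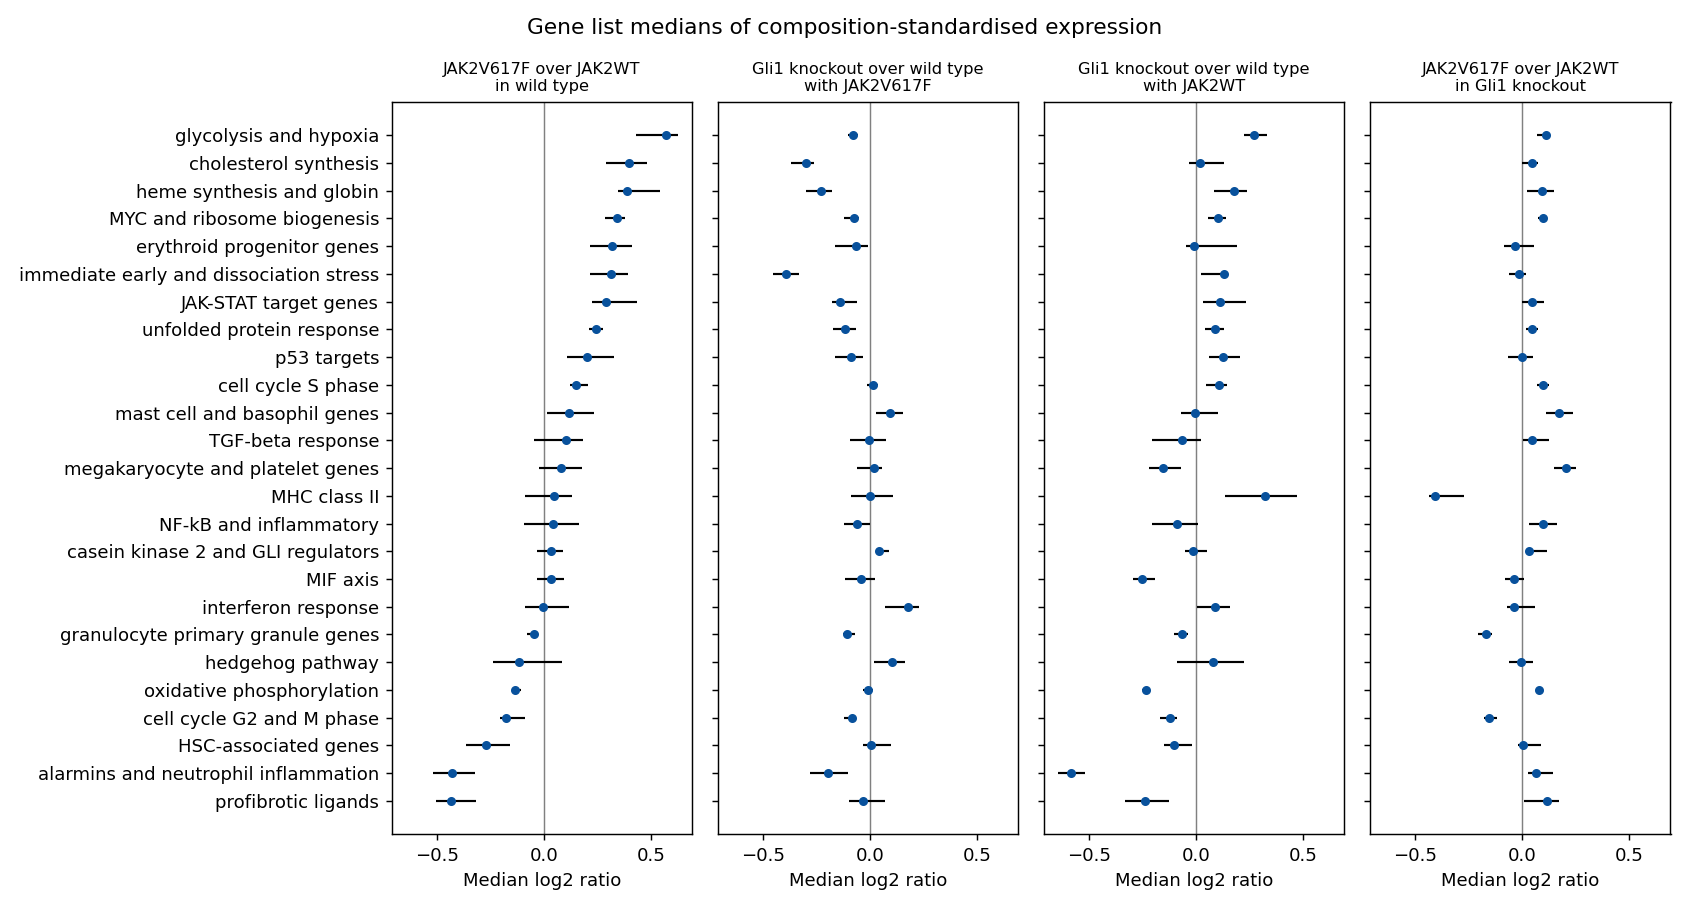
Median log2 ratio of each gene list in the 4 comparisons, with error bars from 200 Poisson redraws of the counts. JAK-STAT targets stand at 0.29 for JAK2V617F in wild type and 0.05 in Gli1 knockout marrow.

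The third comparison, Gli1 knockout against wild type marrow with JAK2V617F in both, asks what the loss of Gli1 does to the mutant marrow. Erythroid-like cells were 34.9-fold scarcer in the knockout, HSC/MPP-like cells 2.82-fold more frequent and granulocyte-monocyte progenitors 0.785-fold as frequent. The medians of immediate early, cholesterol synthesis, heme and JAK-STAT genes were lower in the knockout in all 4 compared classes, and those of interferon response genes were higher in 3 of the 4. Lcn2 was 123.5 CPM in wild type and 40.8 CPM in knockout marrow (log2 -1.39), Mt1 stood at -1.03, and Mif was 916.3 and 767.9 CPM (-0.25). Donor sex differed along with Gli1 in this pair.

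Immediate early and dissociation stress genes had a median of -0.39 (-0.45 to -0.33), with 18 of 19 below 0. Fosb stood at -0.75 and Klf6 at -0.74, and the class medians were -0.77 in NK and innate lymphoid cells and -0.01 in HSC/MPP; in sums over all kept cells the list stood at 0.22, Fosb at 0.19 and Klf6 at 0.059. All 17 measured cholesterol synthesis genes were below 0, with a median of -0.30 (-0.37 to -0.26), Idi1 at -0.54 and Fdps at -0.46. Heme synthesis and globin genes stood at -0.23 with Tfrc at -0.72. Hbb-bs, which may be free RNA there, was 36.2 CPM in wild type and 3.59 CPM in knockout granulocyte-monocyte progenitors. JAK-STAT targets stood at -0.14 (-0.18 to -0.06), with 16 of 22 below 0 and Junb at -0.48, and at 0.11 in sums over all kept cells. Alarmins stood at -0.20, with 0.48 in NK and innate lymphoid cells, unfolded protein response at -0.12 and primary granule genes at -0.11, with Ms4a3 at -0.62. Interferon response genes had a median of 0.18 (0.07 to 0.23) over 18 members, with Bst2 at 0.24, but of -0.23 in NK and innate lymphoid cells. Hedgehog genes stood at 0.10 over 3 members, the casein kinase 2 list at 0.05 with Csnk2a1 at 0.32, the MIF axis at -0.04 and profibrotic ligands at -0.03. The remaining lists lay between -0.09 and 0.09. In single classes of these, MHC class II stood at 0.80 and erythroid progenitor genes at -0.89 in monocytes, and S phase and G2 and M phase genes at 0.55 and 0.57 in NK and innate lymphoid cells.

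Gene by gene, S100a9 was higher in the knockout at 0.73, but took the opposite sign at the coarser clustering (-0.72), under the wider naming of clusters (-0.91) and in sums over all cells (-0.15). Higher too were Tpm3-rs7 at 3.40, the heme-binding protein gene Hebp1 at 1.70, the class I gene H2-D1 at 0.77, Bloc1s2 at 0.75 and Ckap4 at 0.60. Lower were the histone gene Hist2h2ac at -1.80, the tetraspanins Tspan32 at -1.15 and Cd63 at -0.81. Hebp1 stood at -0.83 in the sums over all cells. In HSC/MPP, Ctsg stood at -0.86, Ms4a3 at -0.81 and Ltb at 0.57. Cd52 was higher in granulocyte-monocyte progenitors (1.09) and monocytes (1.04), as were Ifi27 (0.87) in the former and S100a10 (1.03) in the latter. S100a8 stood at 0.61 in HSC/MPP, -1.24 in granulocyte-monocyte progenitors and -0.89 in monocytes, and Wfdc21 at -1.16 in the progenitors and Gstm1 at -0.96 in the monocytes. Of the progenitor class, clusters 3, 19 and 20 held 119, 260 and 202 cells in wild type and 124, 260 and 411 in knockout marrow. NK and innate lymphoid cells had Pclaf at 1.5, Stmn1 at 1.30, Zfp36l2 at -1.49 and Klrb1b at -3.53.

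The fourth comparison set Gli1 knockout against wild type marrow with JAK2WT in both, which gives the difference between the genotypes without the mutant kinase and serves as a yardstick between libraries. HSC/MPP-like cells were 3.27-fold and granulocyte-monocyte progenitors 3.19-fold more frequent in the knockout. Counted without lymphoid, plasma cell, plasmacytoid and low-UMI clusters, these ratios were 2.08 and 2.03, and with the looser cell filter that of the progenitors was 1.51; T cells made up 16.5% and the low-UMI cluster 13 held 1635 of the 7226 wild type cells. Alarmin genes were lower within cell classes, with a median of -0.59 (-0.65 to -0.52), S100a8 at -2.99, Wfdc21 at -1.27 and S100a9 at -1.07 (0.057 without the granulocyte-monocyte progenitors). Neutrophils, whose fixed markers include S100a8 and S100a9, had a share ratio of 0.359 in this pair, and the unnamed cluster 18, which Fcnb, Clec4a2 and Wfdc21 lead, of 0.230. Glycolysis genes were higher at 0.27 (0.22 to 0.33), with Pkm at 0.62 and Pfkl at 0.61, and MHC class II genes at 0.32 (0.14 to 0.47), with H2-Aa at 0.71 (-1.33 in sums over all cells). The MHC class II value rests on NK and innate lymphoid cells (0.55), against 0.08 in HSC/MPP, -0.32 in granulocyte-monocyte progenitors and -0.11 in monocytes. Donor sex differed along with Gli1 here too, and the wild type library was the shallowest per cell. Over genes with at least 50 CPM, the standard deviation of log2 ratios was 0.322 here and 0.369 in the first comparison. Both hold that library. It was 0.185 in the second comparison and 0.224 in the third.

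The MIF axis stood at -0.25 (-0.30 to -0.19), with Mif at 855.8 and 720.8 CPM (-0.25), Cd44 at -0.43 and Cd74 at 0.44. Oxidative phosphorylation stood at -0.24, with 21 of 24 genes below 0. Profibrotic ligands stood at -0.24 over 8 members (0.09 in NK and innate lymphoid cells), with Pf4 at -2.10 (0.083 without HSC/MPP) and Ccl5 at 0.68 (-1.62 without NK and innate lymphoid cells), and at 0.15 when members needed 50 CPM. Megakaryocyte and platelet genes stood at -0.16, with -0.23 in HSC/MPP and values above 0 in the other classes. G2 and M phase genes stood at -0.12, with -1.75 in NK and innate lymphoid cells, -0.32 in HSC/MPP, 0.24 in granulocyte-monocyte progenitors and 0.19 in monocytes. JAK-STAT targets stood at 0.11 (0.03 to 0.24), with Junb at 0.70 and Myc at 0.53, and hedgehog genes at 0.08 over 3 members. The remaining lists lay between -0.10 and 0.18, but in NK and innate lymphoid cells primary granule genes stood at -1.11, S phase genes at -0.71 and mast cell and basophil genes at -0.52. In sums over all cells the MHC class II list stood at -0.55 and the JAK-STAT list at -0.29.

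Several genes that differed by genotype with JAK2V617F differed the same way with JAK2WT: Tpm3-rs7 at 3.62, Hebp1 at 1.78, H2-D1 at 1.26, Bloc1s2 at 0.90, Hist2h2ac at -2.02 and Cd63 at -1.68. Cd63 (chromosome 10, 128900989 to 128912822) is a neighbour of Gli1. Tespa1 stood at 0.92, Ltb at 0.91 and the guanine deaminase gene Gda at -1.10. In HSC/MPP, Vim stood at 0.81, Dazap1 at 0.80, Pf4 at -2.41 and S100a6 at -1.36. Ifitm1 was higher in granulocyte-monocyte progenitors (0.92) and monocytes (1.11). The progenitors also had Alas1 at 0.90, Fosb at -1.54 and Tspan32 at -1.35, and the monocytes had Sox4 at 0.88, the galectin gene Lgals3 at -1.56 and S100a6 at -1.35. In NK and innate lymphoid cells, Casp1 stood at 1.82, Cxcr3 at 1.80, Nusap1 at -3.42 and Gzma at -3.80, beside T cells at 16.5% and 1.45% of the libraries. Clusters 0 and 21 held 116 and 53 cells of this class in wild type and 88 and 80 in knockout marrow. Cells of the granulocyte-monocyte progenitor class numbered 111, 153 and 78 in clusters 3, 19 and 20 in wild type and 214, 192 and 168 in knockout marrow. Under the alternatives Ltb, Ccl5, Sox4, Lgals3, S100a9, Pf4 and H2-Aa each took the opposite sign at least once.

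**Figure D3:**
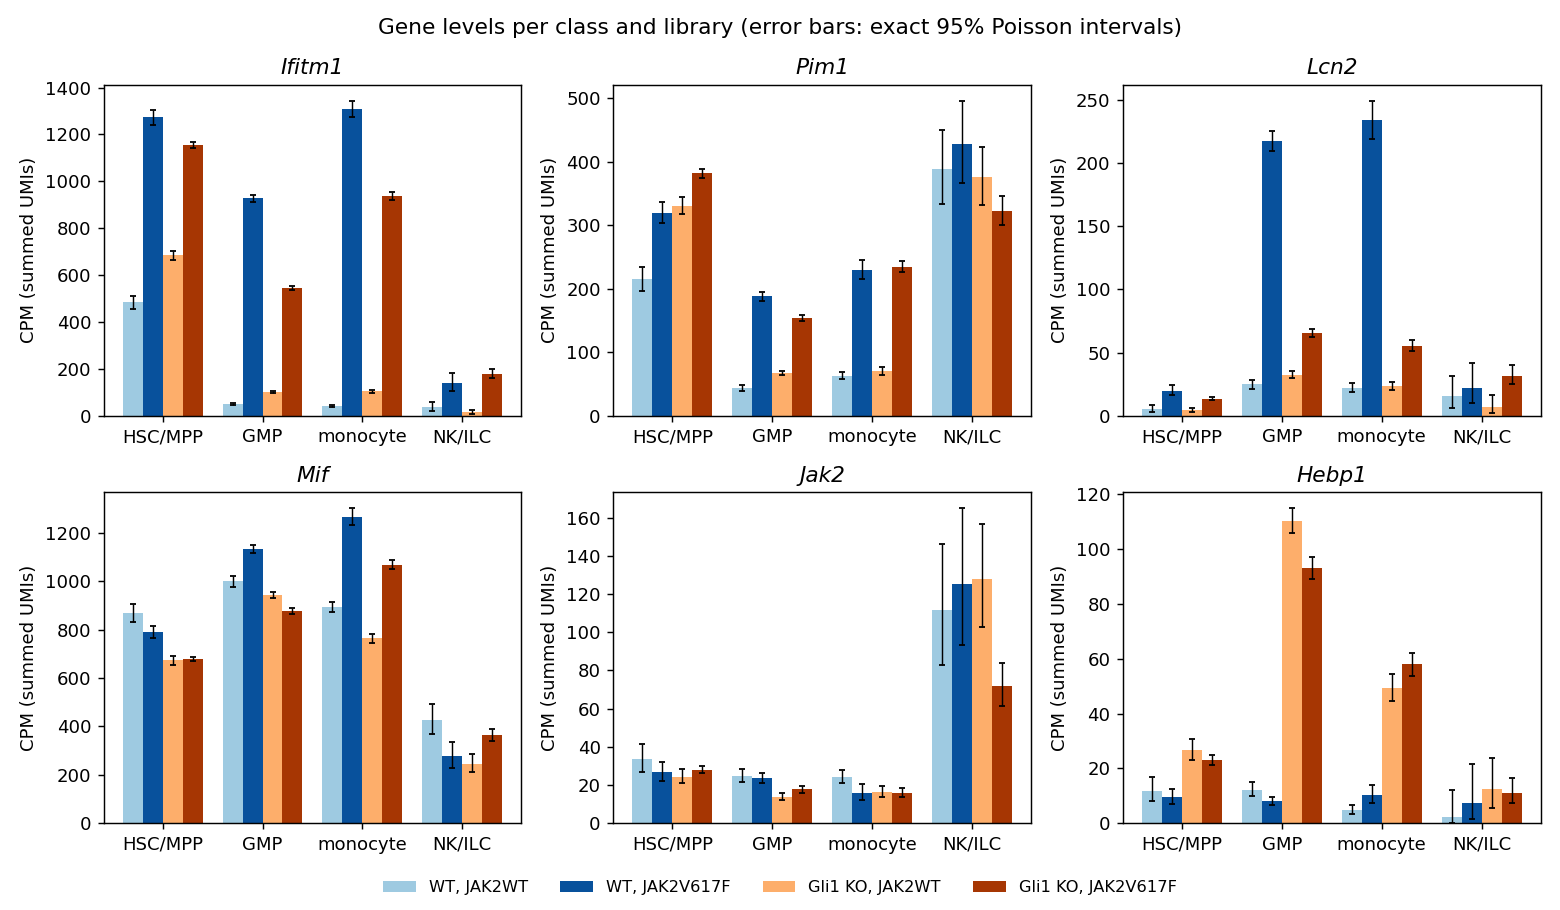
CPM of Ifitm1, Pim1, Lcn2, Mif, Jak2 and Hebp1 in the 4 compared cell classes, as bars for each library with exact 95% Poisson error bars for counting error (GMP, granulocyte-monocyte progenitors and promyelocytes; ILC, innate lymphoid cells; KO, knockout). Pim1 in monocytes stands at 63.3 and 229.5 CPM in wild type and at 70.5 and 234.5 CPM in Gli1 knockout marrow, with JAK2WT and JAK2V617F.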

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

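In this part the test on near-identical gene copies was laid down before its result was seen; the other tests were chosen after the pattern had been seen.

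The difference between genotypes in how the profibrotic ligand list stood with JAK2V617F was 0.55 on the log2 scale (0.12 in Gli1 knockout minus -0.43 in wild type), with opposite signs in the genotypes. The signs were not kept under every alternative: the knockout value was -0.049 with the looser cell filter, -0.014 with no removal of doublets and -0.18 with a list filter of 50 CPM, the wild type value was -0.006 with no list filter, and sums over all kept cells gave 0.60 and 0.018. The B lineage share ratio differed by 7.94 (log2), from -5.57 in wild type to 2.37 in Gli1 knockout, on 7, 6 and 49 cells in 3 of the libraries. The ratio for granulocyte-monocyte progenitors and promyelocytes differed by -2.02 (1.84 in wild type, -0.19 in knockout), and that for mesenchymal stromal cells by -2.32 (1.37 and -0.95). None of these 4 differences was tested, since each group is 1 library. In the 4 libraries progenitor shares were 4.73%, 16.9%, 15.1% and 13.3%, and B lineage shares were 9.67%, 0.204%, 0.158% and 0.818%. For both, wild type marrow with JAK2WT stood apart from the other libraries, so these differences rest largely on it. Without the mutant kinase the progenitor ratio of Gli1 knockout to wild type was 3.19. Mesenchymal stromal shares were 0.609%, 1.57%, 1.55% and 0.802%. Y-linked transcripts, which no comparison uses, had 9089 UMIs in kept cells of Gli1 knockout marrow with JAK2WT and 11925 with JAK2V617F. GFP, the reporter of the retrovirus, had 49 UMIs over all barcodes in wild type with JAK2WT, 132 with JAK2V617F, 9 in Gli1 knockout with JAK2WT and 92 with JAK2V617F.

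Erythroid-like cells made up 35.5% of wild type marrow with JAK2V617F and between 1.02% and 1.32% of the others. Cell filters and doublet removal are argued against as the cause, since the ratio to wild type with JAK2WT was at least 26.9 under each of those settings, and so is free haemoglobin RNA, since cluster 25, whose 10 leading genes hold no haemoglobin, was 17.1-fold more frequent. Less complete depletion of TER119-bearing cells in that 1 library stays open. The haemoglobin-rich cluster held 67.3% of its erythroid cells, against 37.2%, 34.0% and 63.9% in the other libraries, and none of the libraries analysed was made without the depletion. An expansion of erythroid cells by JAK2V617F that needs Gli1 is the biological alternative and may hold. It cannot be told apart from the depletion, from differences between pools of mice or from donor sex, which differed along with Gli1. Nor can it be told apart from the proportion in which GFP-positive and GFP-negative cells were loaded, which is not stated.

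JAK-STAT target genes stood at 0.29 with JAK2V617F in wild type marrow and at 0.05 in Gli1 knockout marrow, at 0.41 and 0.18 without NK and innate lymphoid cells, and at 0.19 and 0.14 in HSC/MPP alone. The wild type value was 0.31 with every cell thinned to 1000 UMIs. Thinning came after filtering, clustering and class naming, so it cannot decide whether the depth gap acted through those steps. Free RNA of erythroid cells is argued against as the source of the wild type value. The median of the 22 members was 0.287 (0.217 to 0.424) with the erythroid profile taken off each class of the JAK2V617F library. The share taken off was set by Hbb-bs (0.380% to 0.619%), and free RNA was assumed to have the mean profile of the erythroid class. Different clusters filling a class are argued against too, as the wild type value was 0.25 with clusters as strata. Differences within a cluster are not covered by this, and the monocyte class is the single cluster 11. A weaker response to JAK2V617F without Gli1 in part of the classes is consistent with these values, as is a lower proportion of transduced cells in that pool, on which GFP counts are too few to decide: 0.881% (0.355 to 1.81) of its granulocyte-monocyte progenitors had a GFP UMI against 2.75% (1.58 to 4.43) in wild type with JAK2V617F, and 0.437% against 0.477% of HSC/MPP cells. The JAK2WT libraries, which set the other side of each ratio, differed in GFP too. It was seen in 0 of 574 progenitors (0% to 0.641%) in Gli1 knockout and 7 of 342 (0.827% to 4.17%) in wild type. Whether this shifted the list was not tested. In sums over all kept cells the order of the genotypes in the JAK-STAT list was the opposite (-0.04 and 0.30).

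Of 3196 autosomal genes with at least 50 CPM in a library, 17 stood at least 1.5-fold apart between the genotypes, in the same direction with both transductions. Over all 3309 genes, sex chromosomes included, this rule gave 11 higher and 10 lower by genotype. For JAK2V617F over JAK2WT in both genotypes it gave 6 higher and 11 lower. Among the 17 were Hebp1, H2-D1, Cd63, Fosb and Klf6. In sums over all kept cells with JAK2V617F, however, Hebp1 stood at -0.83, Fosb at 0.19 and Klf6 at 0.059. A stretch around Gli1 of the strain that carried the mutation is argued against as the whole cause. Of the 17, 1, Cd63, lies within 30 Mb of Gli1, where 0.239 would be expected by chance. The count covers only genes near Gli1, so it cannot decide on strain differences elsewhere in the genome, which stay open. Reads shared with near-identical copies are argued against as the whole cause too, since 4 of the 17 share at least 50% of their 31-base words with another gene (Hist2h2ac, Tpm3-rs7, Gm11361 and Gm10260). Free RNA of plasma cells may account for the immunoglobulin genes Igkc and Ighg1, which are 2 of the 17. Donor sex stays open for the others as well, since the wild type libraries held 1 Y-linked UMI between them against the counts given above in the knockout libraries. For Tpm3-rs7, reads of Tpm3 assigned to this copy may account for its difference, as the summed CPM of both genes differed by at most 1.14-fold between genotypes.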

How the results depend on the processing

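The alternatives added after the data had been seen were clusters as strata, the other denominators of the shares, cluster 2 counted with HSC/MPP, the wider naming of clusters and the scaling without immunoglobulin, haemoglobin, S100a8 and S100a9. The others were chosen before the data were examined. Over all alternatives, 376 of 518 share ratios stayed within their counting interval, as did 1597 of 2300 list medians, 6521 of 8165 standardised gene values and 622 of 888 gene values in single classes. The sign was kept in 486 of the 518 share ratios, 2002 of the list medians, 7786 of the gene values and 883 of the class values. The standardised gene values include both changes of the list filter, which cannot alter a single gene, with 355 unchanged values under each. A change of sign counts below only where the reported value was at least 1.5-fold, or a list median at least 0.2 from 0, a size set after sign changes had been counted. With it, 1 share ratio, 9 list medians, 30 gene values and 5 class values changed sign. Counting every sign change of a value whose own interval excluded no difference, whatever its size, the numbers were 10, 74, 138 and 5. The results followed in full were also picked after their values were seen: the shares of the compared classes and of erythroid cells, Jak2, and the hedgehog, JAK-STAT, profibrotic and MIF lists. For these, every value that left its counting interval is given below, together with every change of sign; the cause was not tested. Median-of-ratios scaling changed no sign of that size, and neither did the scaling without immunoglobulin, haemoglobin, S100a8 and S100a9. Under several settings only 2 or 3 classes kept 100 cells in each library, so the values rest on fewer classes there, and no ratio could be given for plasmacytoid dendritic cells against the library that held none. Few counts limit the hedgehog list, which had at most 3 measured members in the standardised values and 4 in a single class, and Gli1, with at most 5 UMIs in the kept cells of a library; neither depth nor low expression is shown to be the reason. Comparisons are numbered as reported: 1 is JAK2V617F over JAK2WT in wild type, 2 the same in Gli1 knockout, 3 Gli1 knockout over wild type with JAK2V617F and 4 the same with JAK2WT.

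With the looser cell filter, HSC/MPP had share ratios of 3.98, 3.32, 3.30 and 3.96 in comparisons 1 to 4. NK and innate lymphoid cells had 3.33 and 1.35 in comparisons 1 and 3, and granulocyte-monocyte progenitors had 1.94, 0.680, 0.529 and 1.51 in comparisons 1 to 4. Monocytes had 0.115, 0.390, 3.48 and 1.02 in comparisons 1 to 4, and MIF genes had log2 -0.12 in comparison 3. JAK-STAT targets had -0.010 in comparison 2, and profibrotic ligands had -0.049 and -0.093 in comparisons 2 and 4. With the stricter cell filter, HSC/MPP had share ratios of 2.45 and 4.40 in comparisons 2 and 4. NK and innate lymphoid cells had 1.67 and 3.65 in comparisons 2 and 4, and erythroid cells had 0.646 in comparison 4. Granulocyte-monocyte progenitors had 2.41, 0.569, 0.628 and 2.67 in comparisons 1 to 4, and monocytes had 0.146, 0.588, 2.35 and 0.585 in comparisons 1 to 4. Lyz2 in monocytes had log2 0.40 in comparison 1, and MIF genes had -0.28 in comparison 1. Profibrotic ligands had -0.12 and -0.34 in comparisons 1 and 4, and Ccl5 had 0.34 and -0.27 in comparisons 2 and 4. Id2 had -0.58 and -0.72 in comparisons 1 and 4, and Jak2 had 0.20, -0.067 and -0.52 in comparisons 2, 3 and 4. Ltb had -0.098 in comparison 4, and Ly6a had -0.29 in comparison 1. Pf4 had 0.026 in comparison 1. With no removal of doublets, HSC/MPP had share ratios of 3.48 and 3.91 in comparisons 3 and 4. Granulocyte-monocyte progenitors had 1.90, 0.589 and 2.55 in comparisons 1, 2 and 4, and monocytes had 0.401 and 0.802 in comparisons 1 and 4. MIF genes had log2 -0.18 in comparison 4, and JAK-STAT targets had -0.030 and -0.20 in comparisons 2 and 3. Profibrotic ligands had -0.014 and -0.21 in comparisons 2 and 3. With a doubled share of doublets, HSC/MPP had share ratios of 2.81 and 3.36 in comparisons 1 and 3. Granulocyte-monocyte progenitors had 2.13, 0.585, 0.635 and 2.32 in comparisons 1 to 4, and monocytes had 0.280, 1.11, 2.06 and 0.518 in comparisons 1 to 4. Lgals3 in monocytes had log2 0.029 in comparison 4, and Lyz2 in monocytes had 0.25 in comparison 1. Sox4 in monocytes had -0.18 in comparison 4, and MIF genes had -0.12 in comparison 3. JAK-STAT targets had -0.024 in comparison 2. With Leiden resolution 0.5, HSC/MPP had a share ratio of 2.65 in comparison 2. Granulocyte-monocyte progenitors had 2.06, 0.758, 0.630 and 1.72 in comparisons 1 to 4, and monocytes had 0.574 in comparison 1. Profibrotic ligands had log2 -0.57 and -0.38 in comparisons 1 and 4, and S100a9 had -0.72 in comparison 3. With Leiden resolution 2.0, HSC/MPP had share ratios of 4.22 and 4.18 in comparisons 1 and 4. Erythroid cells had 21.5 and 0.795 in comparisons 1 and 4, and granulocyte-monocyte progenitors had 0.698 and 0.707 in comparisons 2 and 3. Monocytes had 0.407, 0.685 and 0.906 in comparisons 1, 2 and 4, and hedgehog genes had log2 -0.18 in comparison 4. MIF genes had -0.086 in comparison 1, and profibrotic ligands had -0.043 in comparison 4. With clustering without cell cycle genes, granulocyte-monocyte progenitors had share ratios of 0.719 and 0.683 in comparisons 2 and 3. Monocytes had 0.136, 0.404, 2.73 and 0.920 in comparisons 1 to 4, and Lyz2 in monocytes had log2 0.35 in comparison 1. MIF genes had -0.050 in comparison 1, and JAK-STAT targets had -0.019 in comparison 2.

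With shares counted without clusters 5 and 13, HSC/MPP had share ratios of 2.62 and 2.45 in comparisons 1 and 2. NK and innate lymphoid cells had 1.62 and 1.94 in comparisons 1 and 2, and erythroid cells had 25.4 in comparison 1. Granulocyte-monocyte progenitors had 2.76 and 0.735 in comparisons 1 and 2, and monocytes had 0.559 and 0.745 in comparisons 1 and 2. With shares counted without lymphoid and low-UMI clusters, HSC/MPP had share ratios of 1.51, 2.29, 3.16 and 2.08 in comparisons 1 to 4. Erythroid cells had 14.7 and 0.777 in comparisons 1 and 4, and granulocyte-monocyte progenitors had 1.59, 0.688, 0.879 and 2.03 in comparisons 1 to 4. Monocytes had 0.323, 0.697 and 0.835 in comparisons 1, 2 and 4. With cluster 2 counted with HSC/MPP, HSC/MPP had share ratios of 3.96, 2.28, 2.33 and 4.03 in comparisons 1 to 4. With the wider naming of clusters, granulocyte-monocyte progenitors had share ratios of 2.39 and 2.16 in comparisons 1 and 4. Plasmacytoid dendritic cells had 1.02 in comparison 4, and MIF genes had log2 -0.14 and -0.19 in comparisons 3 and 4. Profibrotic ligands had -0.56 and -0.38 in comparisons 1 and 4, and S100a9 had -0.91 in comparison 3.

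With scaling without the 50 most counted, mitochondrial and haemoglobin genes, profibrotic ligands had log2 values of -0.51, -0.15 and -0.090 in comparisons 1, 3 and 4. With a pseudocount of 1 CPM, JAK-STAT targets had a log2 value of -0.20 in comparison 3. Profibrotic ligands had -0.53 and -0.35 in comparisons 1 and 4. With a pseudocount of 50 CPM, JAK-STAT targets had log2 values of 0.12 and -0.054 in comparisons 1 and 3. Profibrotic ligands had -0.21 and -0.10 in comparisons 1 and 4. With no filter on list members, hedgehog genes had a log2 value of 0.00 in comparison 3. MIF genes had 0.013 and -0.12 in comparisons 2 and 4, and JAK-STAT targets had 0.20 in comparison 1. Profibrotic ligands had -0.006 and -0.004 in comparisons 1 and 4. With a list filter of 50 CPM, hedgehog genes had log2 values of 0.24 and 0.33 in comparisons 1 and 4. MIF genes had -0.14 in comparison 3, and JAK-STAT targets had 0.61 and 0.37 in comparisons 1 and 4. Profibrotic ligands had -0.18, -0.16 and 0.15 in comparisons 2, 3 and 4. With equal class weights, profibrotic ligands had a log2 value of -0.091 in comparison 4. With sums over all kept cells in place of standardisation, hedgehog genes had log2 values of 0.11 and 0.28 in comparisons 2 and 3. MIF genes had -0.26, 0.087, 0.087 and -0.35 in comparisons 1 to 4, and JAK-STAT targets had -0.039, 0.30, 0.11 and -0.29 in comparisons 1 to 4. Profibrotic ligands had 0.018, 0.60, 0.15 and -0.88 in comparisons 1 to 4, and alarmins had 1.19 in comparison 1. MHC class II genes had -0.55 in comparison 4, and HSC-associated genes had 0.30 in comparison 1. Immediate early genes had -0.28 and 0.22 in comparisons 1 and 3, and Ccl5 had -1.09 in comparison 4. Fosb had 0.19 in comparison 3, and H2-Aa had -1.33 in comparison 4. Hebp1 had -0.83 in comparison 3, and Hlf had 0.12 in comparison 4. Id2 had -1.23 and -0.97 in comparisons 1 and 4, and Jak2 had 0.39 and -0.69 in comparisons 2 and 4. Klf6 had 0.059 in comparison 3, and Ltb had -0.11 in comparison 4. Ly6a had -1.27 in comparison 1, and Nfkbia had -0.41 in comparison 1. S100a8 had 0.97 in comparison 1, and S100a9 had 1.253 and -0.15 in comparisons 1 and 3. With the HSC/MPP class left out, MIF genes had a log2 value of 0.098 in comparison 1. JAK-STAT targets had -0.006 and -0.22 in comparisons 2 and 3, and profibrotic ligands had -0.52 in comparison 1. HSC-associated genes had 0.084 in comparison 1, and Pf4 had 0.13 and 0.083 in comparisons 1 and 4. With the NK and innate lymphoid class left out, MIF genes had log2 values of -0.30, 0.032 and -0.30 in comparisons 1, 3 and 4. JAK-STAT targets had 0.18 and -0.044 in comparisons 2 and 3, and profibrotic ligands had -0.14 and -0.44 in comparisons 3 and 4. Ccl5 had 0.33 and -1.62 in comparisons 2 and 4, and Id2 had -0.35 and -0.61 in comparisons 1 and 4. Jak2 had 0.14 in comparison 2. With the granulocyte-monocyte class left out, hedgehog genes had a log2 value of -0.11 in comparison 4. MIF genes had -0.32 in comparison 4, and profibrotic ligands had -0.32 and -0.093 in comparisons 1 and 4. S100a9 had 0.057 in comparison 4. With the monocyte class left out, MIF genes had a log2 value of -0.043 in comparison 1. Profibrotic ligands had -0.52 in comparison 1. With clusters as strata, profibrotic ligands had a log2 value of -0.13 in comparison 3. With cells thinned to 1000 UMIs, hedgehog genes had log2 values of 0.15, -0.12, -0.11 and 0.23 in comparisons 1 to 4. MIF genes had 0.13 and -0.10 in comparisons 2 and 4, and JAK-STAT targets had -0.034 in comparison 2. Profibrotic ligands had -0.51, -0.17 and -0.45 in comparisons 1, 3 and 4, and Jak2 had 0.57 and 0.22 in comparisons 1 and 4.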

Other observations

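Of the tests in this part, the one on free plasma cell RNA was laid down before its result was seen, and the one on stromal cells was chosen after it.

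Mast cells and basophils were a further class that stood apart with JAK2V617F in both genotypes, at 4.14-fold (3.27 to 5.25) its JAK2WT share in wild type and 3.05-fold (2.40 to 3.88) in Gli1 knockout marrow. Within it, cluster 30, led by Fcer1a, Prss34, Mcpt8 and Il4, held 48 cells in wild type and 43 cells in Gli1 knockout marrow with JAK2V617F, and 0 cells in either library with JAK2WT. Most of the class was cluster 26, with 659 cells, whose leading genes also hold the fixed eosinophil markers Prg2 and Prg3. Its marker score was 2.20 for mast cells and basophils and 1.86 for eosinophils. Neutrophils were 3.23-fold (2.59 to 4.02) and 6.95-fold (4.59 to 10.5) more frequent with JAK2V617F. Counted without lymphoid, plasma cell, plasmacytoid and low-UMI clusters, the ratios were 1.845 and 2.39 for mast cells and basophils and 1.44 and 5.44 for neutrophils. Ifitm1 was higher with JAK2V617F in both genotypes in monocytes, where it measured 43.0, 1308, 103.9 and 935.9 CPM in the 4 libraries, and in granulocyte-monocyte progenitors, where it measured 48.8, 926.8, 101.1 and 545.4 CPM.

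GFP was detected in few cells. In wild type marrow with JAK2V617F, 41 of 1221 erythroid cells (3.36%, 2.42 to 4.53) and 14 of 197 mast cells and basophils (7.11%, 3.94 to 11.6) had a GFP UMI, and in Gli1 knockout marrow with JAK2V617F 19 of 375 mast cells and basophils (5.07%, 3.08 to 7.80) did. Granulocyte-monocyte progenitors with a GFP UMI numbered 7 of 342, 16 of 581, 0 of 574 and 7 of 795 in the 4 libraries, and HSC/MPP cells 5 of 260, 2 of 419, 0 of 447 and 9 of 2059. In T cells of wild type marrow with JAK2WT, 1 of 1193 cells (0.0838%) had one, at a median of 3395 UMIs per cell. Too few UMIs were seen to sort cells into transduced and untransduced.

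Stromal cells of the Gli1 knockout libraries may stem from the female recipients. Of the stromal cells with Xist or Y-linked UMIs, 96.5% of 57 with JAK2WT and 69.05% of 42 with JAK2V617F had Xist and no Y-linked UMI. Among HSC/MPP cells 1.28% and 0.127% did, among T cells 29.03% of 31 and 19.44% of 36, and among plasma cells 6.69% of 254 and 1 of 40, so such cells were not limited to the stroma. Free RNA and the small number of cells leave open how many of the stromal cells with Y-linked UMIs came from the donors.

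Immunoglobulin UMIs in HSC/MPP, granulocyte-monocyte progenitor and monocyte cells may be free RNA of plasma cells. The ratio of Jchain to Igkc in these classes lay within 2-fold of that over all barcodes in 12 of 12 pairs of class and library. The Jchain values reported above, -2.79 and -2.40 with JAK2V617F, may have the same source.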
